A study of Gallus gallus with 2 samples.

How the data were processed

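FOXO1 ChIP and input DNA were sequenced from differentiating primary chicken myoblasts, 1 library each, on an Illumina HiSeq2000, per the labels. Chromatin had been sonicated to 300 to 500 bp. The groups, FOXO1 ChIP and input DNA, were taken from the sample titles. One peak list was used, made from the ChIP library against the input library. Reads, signal tracks and further files were not analysed here.

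Bowtie2 2.1.0 and HOMER 4.7 are named in the submitters' processing notes. Per the file headers, peaks were called by the authors with HOMER findPeaks in its factor style, centred on the highest pile-up, with a peak size of 203 bp, a minimum distance of 406 bp, a fragment length of 168 bp and at most 1 tag per bp. Per the file headers, a false discovery rate of 0.001 set a threshold of 7 tags, against 0.4 expected per peak over a genome of 1002986341 bp. Of 4479 putative peaks, 823 were removed by the authors for lack of a 4-fold excess and a p of 0.0001 over input, 338 by the same limits over the local 10 kb, and 1 for clonality. This left the 3317 listed. The genome build and annotation are not given in the sources used here, and coordinates are printed as listed (1-based, inclusive).

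Total tags are whole-number counts deposited by the authors. The normalized tag count is a signal that the authors scaled to 10000000 tags, and the input tags are a signal that the authors scaled to the depth of the ChIP library. The focus ratio is a fraction from 0 to 1, deposited by the authors as the share of tags placed as in a focused peak. The score is the authors' tag number after limiting tags per position. The fold over input and fold over the local 10 kb are ratios computed by the authors, as is a clonal fold. The p-values over input and local region are unadjusted Poisson p-values by the authors, with 6 of the p-values over input listed as 0. Some listed peaks hold 5 or 6 total tags, under the threshold of 7, while all scores are 7 or more; the header does not say how the counting of the tags and scores differs.

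Depth is given in the header for the ChIP library alone, 2207278 tags. Input tags were recovered here from total tags divided by fold. These quotients were whole multiples of 0.053, and a value at the midpoint below the first step was read as 0 tags. Of the 3309 peaks whose printed fold resolves the step, 99.9% came within 0.1 of a whole tag. For the other 8 the nearest whole number was used. The step corresponds to an input of 41662248 tags if input was counted over the ChIP width, and to fewer if over a wider window, which the header does not say.

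From these values the number, tags and folds of peaks were described. The fold interval of a peak is the exact (Clopper-Pearson) 95% binomial interval of ChIP against input tags. Shares also have exact 95% intervals, and peak numbers have Poisson 95% intervals. A fold against 0 input tags was computed against a floor of 3 tags. Peaks were counted in chromosome classes 1 to 5, 6 to 10, 11 and above, and Z, and tested with exact binomial tests. Median folds were compared by permutation with 100000 resamples, and bootstrap intervals used 2000 draws. The closing section uses 10000 random placements of peaks on the same chromosome and Poisson tests of 1 Mb windows. Adjustment was by Benjamini-Hochberg with a threshold of 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

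The tests, chromosome classes and several other settings were fixed before the data were examined, on the assumption that a genome of the file's build would be at hand. It was not, so chromosome length was replaced by the highest peak end on each chromosome. These ends sum to 996616210 bp, 99.4% of the genome size in the header. Planned analyses of transcription start sites, annotation classes, FOXO and other motifs, GC content, repeats and 14 gene lists, and the tests of peak strength by location, were not run. A table of chicken genes of another assembly was not used. The exact test against input, comparisons of fold between classes, correlation with length, linking of peaks into groups, thinning of scores (binomial draws, keeping scores of 7 or more) and placement tests were added after the data were seen.

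Peaks to name were fixed by rule as the 25 with the smallest p-value (ties by fold, then tags). The rule also named genes from the fixed lists, the genes with most peaks and 10 genes of muscle and FOXO1 biology; these need assigned genes and are not reported here. The remaining members of the chromosome 1 group, the chromosomes named singly and the windows were chosen after their values were seen.

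The tests were checked on simulated data with 3317 peaks. With peaks placed uniformly, a class passed in 4 of 100 runs. Those peaks were drawn independently, without the grouping of neighbours in the list, so this rate need not hold for the listed peaks. A density set to 2 times on chromosomes 11 and above was recovered as 1.90. The neighbour count passed in 2 of 40 uniform runs, and 150 added neighbours gave an excess of 139.9. A known input step was recovered with a ratio of 1.00 to the true step, and 100% of simulated input tags came back. Alternatives were stricter lists (the 1659 peaks with the smallest p-value, a fold of at least 8, a score of at least 12), merging of peaks within 1 kb, leaving out the chromosome 1 group or peaks with 100 or more input tags, and other windows.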

Results

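The series asked where FOXO1, a forkhead transcription factor known to act in muscle growth and atrophy, was bound on the chicken genome early in myoblast differentiation. Myoblasts came from thigh muscle of 11-day chicken embryos and were kept in medium with 20% fetal bovine serum, then moved to 2% horse serum to differentiate. Chromatin immunoprecipitation with a FOXO1 antibody gave 1 ChIP library, and chromatin without antibody gave 1 input library. The design therefore holds a single comparison, ChIP against input, with 1 library on each side. There was no replicate, so no value below has a replicate check, and each test compares these libraries or describes this peak list, not conditions. Folds, scores and p-values per peak are those of the authors' peak caller unless stated otherwise. Exact and Poisson intervals cover counting error only and take tags or peaks as independent. Reads amplified by PCR are not independent molecules, so intervals on tags can be too narrow. Bootstrap intervals cover the spread over listed peaks only.

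The ChIP library held 2207278 tags, and the authors' caller listed 3317 FOXO1 peaks, each 203 bp wide. They lay on 29 chromosomes, 1 to 28 and Z. Most were low: the median peak held 7 ChIP tags (interquartile range 7 to 9, range 5 to 1507), and 2819 peaks (85.0%) held 6 to 9 tags. A count of 7 tags has a Poisson 95% interval of 2.81 to 14.4, so the order of peaks within this majority was not resolved. At the other end, 33 peaks held 20 tags or more and took 20.4% of the 32860 tags at peaks. Tags at peaks made up 1.49% of the library.

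The scores fell off more slowly than the uniform background given in the file header would. Of the peaks, 44.0% had the lowest listed score of 7, where a Poisson rate of 0.4 tags per peak width puts 95% of windows scoring 7 or more. There were 0.557 times as many peaks with a score of 8 as with 7, against 0.05 under that rate. This compares the list with a uniform rate only; a rate that varies along the genome also gives a longer tail.

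**Figure D1:**
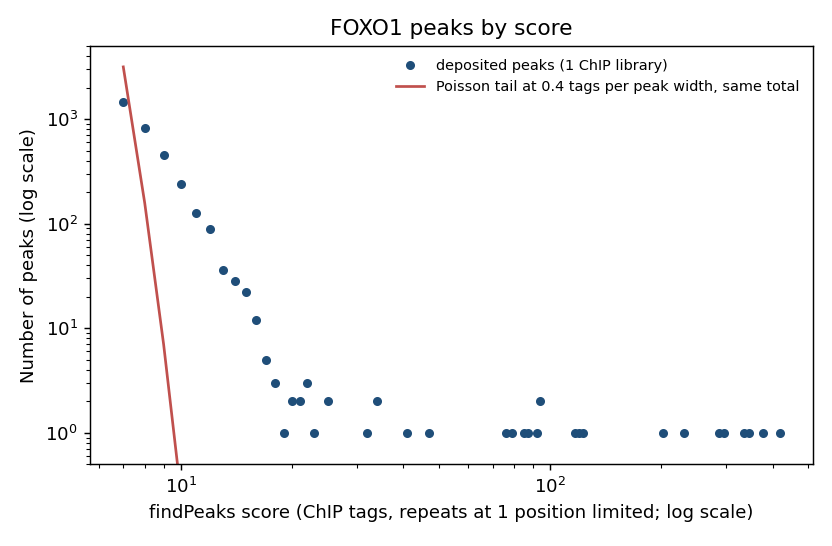
Number of FOXO1 peaks (vertical axis, log scale) at each peak score (horizontal axis, log scale) in the 1 ChIP library; the line is the Poisson tail at the background rate of 0.4 tags per peak width, scaled to the same 3317 peaks. The 1459 peaks with a score of 7 lie under the line, and the points at 8 and above lie over it.

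Against input, the median peak was 13.21-fold enriched (bootstrap 95% interval over peaks 13.07 to 13.32, interquartile range 9.44 to 18.87). The lowest fold was 4, the minimum that the caller required. The median fold over the surrounding 10 kb of the ChIP library was 13.8. The input was the deeper side: a median of 11 input tags (interquartile range 8 to 15) stood behind each peak's ratio. With counting error in both libraries, 2001 peaks (60.3%) had a lower 95% limit of the fold above 4, and 442 had one above 8. All 3317 peaks passed an exact one-sided binomial test of ChIP against input tags after Benjamini-Hochberg adjustment, with a largest adjusted p of 0.000295. The list had already been selected on fold and p, so that count is not an independent test of the peaks, and the adjustment covers listed peaks only.

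The highest tag counts came from a few places, and one of them was a single stretch of chromosome 1. Between 100348374 and 100411694 (63.3 kb), 14 peaks held 3794 tags, or 11.5% of all tags at peaks (exact 95% interval 11.2 to 11.9). No other group of peaks linked by gaps of at most 10 kb had more than 4 members. The tallest of the 14 lay at 100378285 to 100378487, with 714 tags and an 18.02-fold enrichment (95% interval 16.2 to 20.0). The peak at 100411492 to 100411694 had 352 tags and the highest fold of the group, 24.07 (20.5 to 28.3). The lowest, at 100405591 to 100405793, had 15 tags and 5.24-fold (2.75 to 9.43).

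The input was also high there. The 14 peaks had a median of 261 input tags (range 54 to 1019), against 11 at other peaks. Their pooled fold was 13.8 (95% interval 13.2 to 14.4), against 11.9 (11.7 to 12.1) for the other peaks pooled. The medians went the other way, 12.8 for the 14 peaks (range 5.24 to 24.07) and 13.21 for the others, and neither difference was tested. The stretch stood apart in tag number in both libraries.

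**Figure D2:**
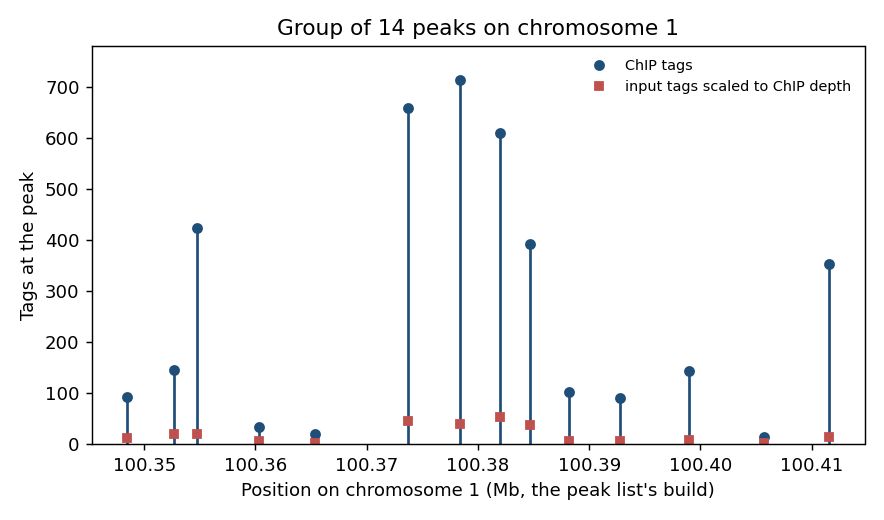
ChIP tags (circles) and input tags scaled to the ChIP depth (squares) at each of the 14 peaks between 100348374 and 100411694 of chromosome 1, by position in Mb, from 1 library each. ChIP tags run from 15 to 714, and at each peak they lie above the scaled input.

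Of the 25 peaks with the smallest p-values, 15 lay on chromosome 1, 11 of them in that stretch, and the 25 covered 8 chromosomes. Outside it, the peak with most tags was on chromosome Z at 68963760 to 68963962. It held 1507 ChIP tags and 3010 input tags, a 9.45-fold enrichment (95% interval 8.88 to 10.1). Its score, which limits repeated tags at 1 position, was only 117, so its tags were 12.9 times its score, against a median of 1 over all peaks. That score lies below the peak's input scaled to the ChIP depth, 159 tags. The fold and its interval therefore rest on repeated tags, and whether input tags were limited in the same way is not stated. On chromosome 1, the peak at 152081702 to 152081904 had 304 tags at 8.51-fold (7.41 to 9.76). The peak at 18025904 to 18026106 had 97 tags at 10.34-fold (7.99 to 13.3), and that at 135634956 to 135635158 had 35 tags at 11.59-fold (7.38 to 18.0).

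Near the highest listed position of chromosome 23, a peak at 5721121 to 5721323 had 329 tags at 5.48-fold (4.83 to 6.20), with a neighbour at 5721644 to 5721846 of 46 tags at 7-fold (4.88 to 9.90). On chromosome 19, a peak at 66546 to 66748 had 130 tags at 10.44-fold (8.36 to 12.99). Also on chromosome 19, adjoining peaks at 170330 to 170532 and 170944 to 171146 had 102 and 104 tags. Their folds were 4.36 (3.48 to 5.41) and 4.76 (3.80 to 5.92), so the lower limits fell under the 4-fold that the caller required.

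Of these 25 peaks, 19 had 100 or more input tags. Over the whole list 22 peaks had as many, and they held 19.6% of the tags at peaks. Of the other 6, the peak on chromosome 1 at 145707537 to 145707739 had 21 ChIP tags and 12 input tags, the latter close to the list's median of 11, a 33.0-fold enrichment (15.5 to 73.6). Another 4 of the 25 ranked high with 3 or fewer input tags. On chromosome 2 at 394665 to 394867, 17 ChIP tags stood against 3 input tags, a ratio of 107 (30.9 to 570). On chromosome 4 at 13835612 to 13835814, 16 stood against 3, a ratio of 100.7 (28.8 to 539). On chromosome 20 at 2448586 to 2448788, 13 stood against 2, a ratio of 123 (27.8 to 1120). The peak on chromosome 11 at 19142041 to 19142243 had 10 ChIP tags and 0 input tags. Against a floor of 3 input tags it was at least 62.9-fold enriched. That floor leaves out the counting error of the ChIP tags; with it, the lower end of the exact 95% interval was 42.3-fold. In all, 10 peaks had 0 input tags.

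Peaks were not spread over the chromosomes by length. The short chromosomes, 11 and above, which are known to be gene-rich in birds, carried 1200 peaks at 7.03 per Mb (95% interval 6.64 to 7.44). The long chromosomes 1 to 5 carried 1513 peaks at 2.51 per Mb (2.38 to 2.64), and chromosomes 6 to 10 carried 539 at 3.78 per Mb (3.47 to 4.11). Chromosome Z, the sex chromosome that males hold as a pair and females as a single copy, carried 65 peaks at 0.816 per Mb (0.630 to 1.04). Chromosomes 11 and above were 2.81 times as dense in peaks as chromosomes 1 to 5 (2.60 to 3.03), and Z 0.326 times as dense (0.2501 to 0.418). With the scores on chromosomes 11 and above thinned by the ratio of ChIP tags around peaks, which assumes that peak tags scale with those tags, 3.55 peaks per Mb were left, 1.42 times the density of chromosomes 1 to 5 (1.11 to 1.65).

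Each class differed from its share of the covered length in an exact two-sided binomial test with Benjamini-Hochberg adjustment over the 4 classes. Chromosomes 11 and above held 2.11 times the number given by length (exact binomial, adjusted p = 1.9e-151) and chromosomes 6 to 10 held 1.14 times (adjusted p = 0.00163). Chromosomes 1 to 5 held 0.753 times (exact binomial, adjusted p = 1.55e-67) and Z 0.245 times (adjusted p = 2.07e-51). Among peaks with a score of at least 12, chromosomes 6 to 10 held 0.855 times their share (28 peaks, exact binomial, adjusted p = 0.45), too few peaks to show a change. Within chromosomes 6 to 10, the excess came from chromosomes 8, 9 and 10, with 4.22, 4.15 and 4.90 peaks per Mb. Chromosomes 6 and 7 had 3.21 and 3.13, below the density of the whole list. Peaks were treated as independent, which neighbouring peaks are not, and length was taken as the highest peak end on each chromosome. In 1 Mb windows of the autosome classes, the variance around each chromosome's own mean was 1.97 to 2.81 times that mean. These p-values are therefore too small and the density intervals too narrow.

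Chromosome by chromosome, density followed length. Chromosome 16, covered over only 0.448 Mb, had 22.3 peaks per Mb (95% interval 10.7 to 41.0, 10 peaks), and chromosome 25 had 14.8 (10.1 to 20.8). Chromosomes 23, 26 and 28 had 12.2, 12.04 and 11.8 per Mb. Chromosome 11 had 4.12 (3.26 to 5.14), and chromosome 2, the lowest autosome, had 2.19 (1.96 to 2.44). Over the 29 chromosomes, log10 density against log10 covered length gave Pearson's r = -0.906 and Spearman's rho = -0.951 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). Without chromosomes 1 and 16, the farthest from the median length, r was -0.901. Within the 18 chromosomes from 11 upward r was -0.877. Length enters both axes, and the 4 correlations computed all had an adjusted p of 1e-05.

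**Figure D3:**
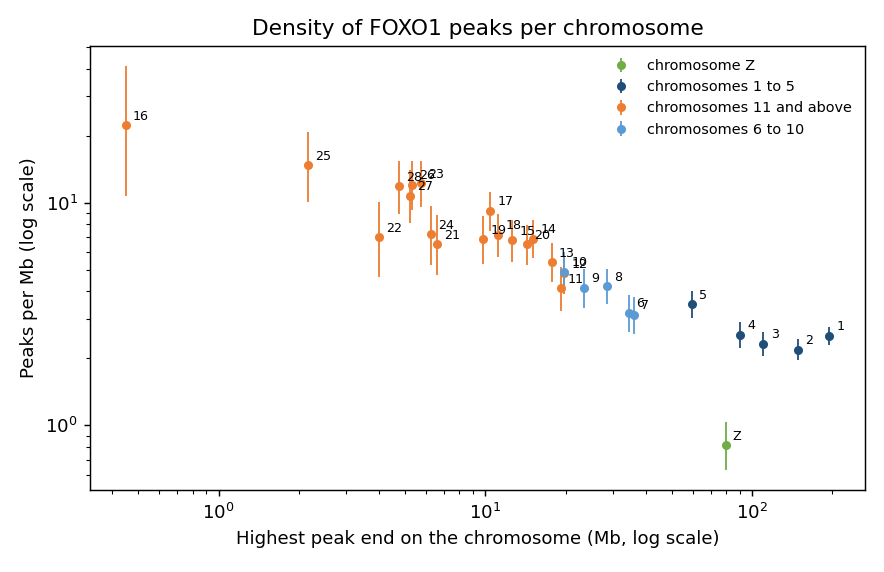
FOXO1 peaks per Mb (vertical axis, log scale) against the highest peak end on each of 29 chromosomes (horizontal axis, Mb, log scale), coloured by chromosome class; bars are Poisson 95% intervals from the peaks of 1 ChIP library. Density falls from 22.3 per Mb on chromosome 16 to 2.19 on chromosome 2, and chromosome Z lies lowest at 0.816.

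Peaks on chromosome Z were fewer, and over the full list their ratio to input was higher. Their median fold was 18.87, against 13.21 on chromosomes 1 to 5 (two-sided permutation test of medians, 100000 resamples, adjusted p = 0.00153 over 3 comparisons). Among the 1659 peaks with the smallest p-value the difference was 3.78, with 40 peaks on Z, and missed the threshold (permutation test, adjusted p = 0.0662). On a log2 scale the mean fold was 0.57 higher on Z (4.43 against 3.87, permutation test, adjusted p = 3e-05). The median number of ChIP tags was 7 in both, and input tags were lower on Z, with a median of 7 against 11 (permutation test, adjusted p = 9e-05). With most ChIP counts near the common threshold of 7 tags, a lower input by itself gives a higher fold. The fold is therefore not separate evidence of stronger peaks on Z. The median folds of chromosomes 6 to 10 and of 11 and above were 13.21, the same as on chromosomes 1 to 5. That is the tied value of peaks with 7 ChIP and 10 input tags, so equal medians can hide small differences. Mean log2 folds were 3.85 on chromosomes 6 to 10 and 3.81 on 11 and above, against 3.87 (permutation test, adjusted p = 0.69 and 0.0954). Tags in the 10 kb around peaks were denser on chromosomes 11 and above, with a median of 0.642 per peak width against 0.518 on chromosomes 1 to 5 (permutation test, adjusted p = 3e-05), and sparser on Z (0.394, adjusted p = 0.00015).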

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

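The stricter lists by p-value and by fold and the merging of peaks, for the number of peaks and the chromosome classes, were set before the data were examined; every other setting below was chosen after the data were seen. Of 82 alternatives over 14 results, 66 kept direction and side of the threshold or stayed within the counting limits. The density of chromosomes 6 to 10 was 0.855 times its share at a score of at least 12 (exact binomial, adjusted p = 0.45, 28 peaks). That is too few peaks to show a change. Over chromosomes 1 to 5 the density ratio was 1.01 (0.646 to 1.54) at that score, a range that holds the 1.51 of the full list. The excess in the first 100 kb missed the threshold at a fold of at least 8 (1.35 times, placement permutation p = 0.189, 2947 peaks). The higher median fold of Z was 3.78 above chromosomes 1 to 5 in the 1659 peaks with the smallest p-value (permutation, adjusted p = 0.0662, 40 peaks on Z, so fewer were tested), and the normalized tag count differed by 0. Against the local 10 kb, the median fold of Z was 18.8 against 14.8 on chromosomes 1 to 5 (permutation, adjusted p = 0.0002), and median folds were lower than on chromosomes 1 to 5, by -1.18 for chromosomes 6 to 10 (permutation, adjusted p = 0.0002) and by -2.68 for 11 and above (adjusted p = 3e-05). Median ChIP tags were 7 in every class, so these local folds mostly mirror the local tags. The density ratio of chromosomes 11 and above to 1 to 5 was 2.45 at a score of at least 12 and 1.42 with scores thinned by local tags. Stricter counts are smaller by construction: 2148 peaks passed Bonferroni adjustment and 2001 had a lower fold limit above 4. The median fold was 18.87 in the 1659 peaks, 14.16 at a fold of at least 8 and 14.23 at a score of at least 12. The chromosome 1 group took 8.36% of scores and 10.1% of input tags. Planned settings that need a genome were not run. No paired analysis was possible because each group has 1 library. With a median of 7 tags, differences between most single peaks were not detectable.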

Other observations

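The placement and window tests, all tests of the chromosome 1 group, the tests of input and of thinned scores on chromosomes 11 and above, their density ratio without the chromosome 1 group and the drawn input ratio for Z were chosen after the results were seen.

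Peaks lay next to each other more often than random placement on the same chromosome gave. There were 247 pairs of adjacent peaks within 10 kb, against a mean of 148 in 10000 placements (95% range 126 to 171; two-sided permutation p = 0.0002, the smallest they can give). Random placement within the same 1 Mb left a ratio of 1.35, and leaving out the chromosome 1 group as well left 1.29 (permutation p = 0.0004). The first 100 kb of chromosomes held 34 peaks, on 19 chromosomes, against 19.6 at random (12 to 28; permutation p = 0.0028). Placement within the same 1 Mb gave 1.44 times (permutation p = 0.0354), and with a fold of at least 8 the ratio was 1.35 (p = 0.189). These peaks had a median fold of 10.1 and a median of 15 input tags.

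In windows of 1 Mb, 13 of 983 held more peaks than their chromosome's own density gave (Poisson test, Benjamini-Hochberg adjusted). The first Mb of chromosome 4 held 16 peaks against 2.55 expected (exact Poisson, adjusted p = 1.37e-05), and the next Mb held 14. The first Mb of chromosome 2 held 13 peaks, that of chromosome 1 held 11 and that of chromosome 13 held 15. On chromosome 20, the window from 5000001 to 6000000 held 19 peaks against 6.51. Peaks per window varied more than a Poisson count would, so these p-values are too small. Around each chromosome's own mean, the variance was 1.97 times the mean on chromosomes 1 to 5, 1.99 times on 6 to 10, 2.81 times on 11 and above and 1.11 times on Z.

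The 14 peaks within 63.3 kb of chromosome 1 held high tag counts in both libraries. Extra copies, or a repeat collapsed in the assembly, would raise ChIP and input alike. Of the 14 peaks, 13 passed an exact binomial test of a ChIP to input ratio of 1, on tags or score, whichever was lower. With Bonferroni adjustment over all peak widths of the genome, 327 of all 3317 peaks passed it. ChIP tags at the 13 peaks thus exceeded input beyond counting error. Listed peaks had to be 4-fold over input, so at such tag counts that filter largely set the outcome, which is no independent support. Nor does the test address extra copies on top of an ordinary enrichment. The median fold was 12.8 for the 14 peaks and 13.21 for the others. Stacks of tags at identical positions are argued against as the whole cause by scores 13.6 times those of other peaks (9.69 to 39.6). For the high input, extra copies remain a candidate explanation: median input was 23.7 times that of other peaks on chromosomes 1 to 5 (10.5 to 50.5). For the ChIP tags in excess of input, DNA from another source in the ChIP preparation stays open, because no reads were examined. The median focus ratio of 0.726 does not decide it, and no biological explanation was tested.

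Chromosomes 11 and above carried more peaks per Mb than chromosomes 1 to 5. Calls near the tag threshold as the whole cause would bring the ratio of densities to at most 1.2 at a score of 12 or more; it was 2.45 (1.82 to 3.28), above that limit, though its lower end missed the value of 2 set beforehand for excluding this cause; without the chromosome 1 group it was 2.78 (2.05 to 3.76), past that value. Lower input on chromosomes 11 and above is argued against by a ratio of median input tags of 1 (1 to 1.09), within the limits of listed peaks. A higher general ChIP background remains possible: the ratio of median local tags was 1.24 (1.2 to 1.33), between the limits of 1.2 and 1.5. Those limits were likewise written before the test but after the densities were seen. Local tags were measured only around peaks. Thinning scores by that ratio brought the density ratio from 2.81 to 1.42 (1.11 to 1.65), a simulated value that rests on peak tags scaling with local tags and does not settle how much of the excess is background; no biological explanation was tested.

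Chromosome Z carried fewer peaks per Mb. A candidate explanation is fewer copies of Z than of autosomes, as in cultures that include female cells; the ratio of median input tags at peaks was 0.636 (0.545 to 0.818). Thinning the scores of chromosomes 1 to 5 to that ratio left 0.544 peaks per Mb (0.502 to 0.585), below the 0.816 of Z (0.630 to 1.04). With the ratio's own error included, a step added after that range was seen, the range was 0.306 to 1.32 and held the density of Z. The verdict turns on that step, so the test leaves copy number open.

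A hypothesis for the dense start of chromosome 4 is that its short arm, known to descend from a microchromosome, may carry peaks at the density of one. Peaks at 2 to 20 Mb, leaving out the dense start itself, were 1.63 times as dense as beyond 20 Mb (1.18 to 2.23; exact binomial, adjusted p = 0.0125 over 6 chromosomes). The ratio was 0.771 on chromosome 1 (0.530 to 1.09) and 0.735 on chromosome 5 (0.520 to 1.022), with intervals wholly below that of chromosome 4. It was 1.43 on chromosome 2 (1.04 to 1.93) and 1.38 on chromosome 3 (1.01 to 1.87), with intervals that overlap it. A ratio set apart from all other long autosomes, as the hypothesis asked, was therefore not shown. These tests also take peaks as independent, while the variance of peaks per window on chromosomes 1 to 5 was 1.97 times the mean. The p-value for chromosome 4 is thus too small and the intervals are too narrow. Its separation from chromosomes 1 and 5 is therefore uncertain as well.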
